A study of soil metagenome with 64 samples.

How the data were processed

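Soil was taken from 64 quadrants of a long-running global change experiment on annual grassland in California, 14 years after treatments started, per the labels' protocols. The 16 treatments combine 4 factors, each present or absent: added nitrate (7 g nitrogen per m2 per year), added precipitation (50% more), warming (1.5 °C) and elevated CO2 (680 against 380 ppm). Each treatment has 4 replicates, drawn from the 4 replicate blocks that an experimental fire left unburned. CO2 and warming were applied to round plots, and nitrogen and water to quadrants within them. DNA was obtained from 5 g of soil by freeze-grinding, purified on a gel, labelled with Cy3 by random priming and hybridised to a functional gene array, per the labels' protocols.

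The deposited intensity values are 1 linear Cy3 signal per probe and sample for 68694 probes. They come with the gene name, gene category, organism and lineage of each probe. A probe that was not called detected in a sample has an empty cell in the deposited table. The background correction, the signal-to-noise threshold for a detected probe and any scaling between arrays are not given in the sources used here. The totals per array lay within 1.35-fold of each other while the number of detected probes varied 2.70-fold, which points to a scaling of arrays before deposit. No value was identical between 2 arrays throughout (0 pairs of identical arrays), and every column of values belonged to a listed sample.

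Gene names were merged ignoring case and separators, which left 792 of 795 names. A gene family here is the set of probes that carry the same gene name. Its relative abundance was the summed signal of its detected probes as a percent of the summed signal of the array, with undetected probes counted as 0. Of the 785 families with any detected probe, 526 had at least 3 such probes and a value above 0 in all 64 samples, and they held 99.21% of the signal. Log2 relative abundance was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), with Benjamini-Hochberg adjustment over the families and a threshold of 0.05. All tests were two-sided.

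The labels do not number the plots. A plot was taken as the 4 quadrants that share a CO2 setting, a warming setting and a replicate number, because the identifiers in their titles form runs of 4. Nitrogen, water and their interactions were tested within plots, with plot as a fixed block, on 32 quadrants with against 32 without the factor. CO2, heat (the label for warming) and their interaction were tested on 16 plot means, 8 plots against 8, with the replicate number as block, since the plot was the unit that received them. Each of the 15 treated groups was also compared with the untreated control in 1 model of the 16 groups, 4 quadrants against 4, with plot as a random block (consensus correlation 0.084). These 15 comparisons share the same 4 control arrays, so their chance values are not independent. The same models were fitted to the summed share of 31 lists of gene families for processes in carbon, nitrogen, phosphorus and sulphur cycling, stress and resistance, to 38 domains and phyla taken from the lineage column, and to 25908 single probes with a signal in at least 48 samples.

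The number of detected probes, the Shannon index of probe signals and the total signal were compared by permutation. Nitrogen and water labels were shuffled within plots 100000 times. CO2 and heat labels were exchanged among the plots of each replicate number, which gives 1296 arrangements and an exact test. Composition was compared by PERMANOVA with vegan 2.7.1 on Bray-Curtis distances with 9999 permutations under the same restrictions. Tables were read with the R package data.table (version 1.17.8), and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

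The lists, the models and the rule for named genes were fixed before the data were examined. For each main effect the rule takes the 10 largest rises and 10 largest falls among families past the threshold. If fewer than 5 pass, it takes the 5 families of smallest p, given as values alone. It further takes up to 4 members of each list with the smallest p, 5 probes per direction past the threshold, and for interactions and single treatments the 5 families of smallest adjusted p among those past it. The text gives a part of what the rule takes, and the choice of that part was made after values were seen. Tests of interactions on lists and taxa were added after the data were seen.

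Other settings were tried 1 at a time: the deposited values without further scaling, arrays divided by the median of the probes detected on all arrays, other probe filters (detected in all 64 or in at least 48 samples, dim probes removed), the mean log2 signal in place of the sum, other minimum probe numbers, no block or another block, and each replicate number left out in turn. Further settings were added after the data were seen: the number of detected probes as a covariate, 2 principal components as covariates, and models without the 3 arrays of fewest detected probes or without control replicate 1.

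The fits were tested on simulated data of 526 families with the spread of the real arrays, independent normal noise and 50 families changed per fold size. All fold sizes (1.1, 1.2, 1.5 and 2) were changed in the same fit. With a 1.1-fold change, 54% of changed families were recovered for nitrogen, 66% for water, 46% for heat and 38% for CO2. A 1.2-fold change gave 82% for nitrogen, 82% for water, 74% for heat and 76% for CO2. For nitrogen against control, 40% were recovered at 1.2-fold and 86% at 2-fold. For the interaction of water and CO2, 44% were recovered at 1.2-fold and 96% at 2-fold. Among 25908 simulated probes, 74% of those changed 1.5-fold were recovered for nitrogen and 74% for CO2. Real arrays share structure that the simulation lacks, so these shares are optimistic. For families they also hold only where many change at once. With few changed families the adjusted threshold is stricter and recovery would be lower. The number of arrays limits the precision of every value.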

Results

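The array gave signals for many microbial genes for nutrient cycling, carbon degradation, stress, and metal and antibiotic resistance. It was run on soil DNA from 64 quadrants of 16 treatments with 4 replicates each. The gene and taxon values below are shares of the signal of an array, not amounts in soil. Between 18760 and 50611 of the 68694 probes had a signal on an array (median 35724.5), which is 27.3% to 73.7% of the probes. The total signal per array, in units of 1000000, was 628 to 851 (median 793). In all 64 samples 4876 probes had a signal, 25908 had one in at least 48 samples, and 3466 had none in any sample. The number of detected probes was 36273 ± 5582 (SD, n = 32) without and 34738 ± 6806 with nitrogen (permutation p = 0.314). The difference with water was 1418 probes (permutation p = 0.352), that with heat 767 (exact p = 0.478) and that with CO2 -386 (exact p = 0.710), and none passed the test.

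**Figure D1:**
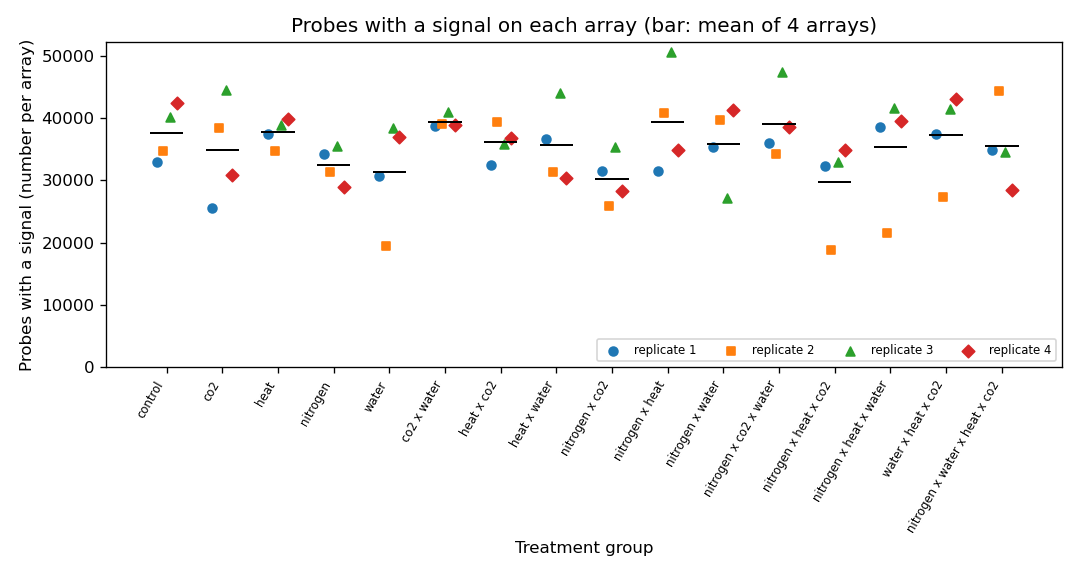
Number of probes with a signal on each of the 64 arrays, by treatment (4 arrays each); symbols mark the replicate number and the bar is the group mean. The arrays span 18760 to 50611 probes, and the array with 18760 is a single replicate of a group whose other arrays lie between 32275 and 34896.

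Bacterial probes gave 89.5% of the signal, fungal probes 6.55%, archaeal probes 2.71% and viral probes 0.364%. Proteobacteria gave 44.6% of it from 29634 probes, Actinobacteria 19.1% from 8107 and Firmicutes 6.80% from 6343. Such shares depend on how many probes the array holds, so they do not rank taxa or genes by abundance in soil. They are parts of 1 total, so a higher share of a large group lowers the shares of the rest. By gene category, carbon cycling took 36.7% of the signal, metal resistance 14.2%, breakdown of organic pollutants 11.3%, nitrogen cycling 9.92%, stress 7.94%, sulphur cycling 5.52% and phosphorus cycling 3.49%. The alpha-amylase genes of Actinobacteria (amyA_Actinobacteria) gave 3.51% of the signal from 1353 probes, the exopolyphosphatase gene ppx 2.37% from 1194, bacterial and archaeal chitinases 2.03% from 1084, the nitrate reductase gene narG 1.83% from 844, the urease gene ureC 1.37% from 645 and the nitrogenase gene nifH 1.32% from 937.

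The nitrogen comparison asks how 14 years of added nitrate relate to the microbial gene pool. The list named dissimilatory nitrate reduction to ammonium holds napA and nrfA, of which nrfA carries out the step that forms ammonium. Its share was 0.591% ± 0.0382 (SD, n = 32 quadrants) without and 0.562% ± 0.0425 with nitrogen, and it was lower with nitrogen in 13 of 16 plots. napA encodes the periplasmic nitrate reductase and differed by -5.91% (95% interval -9.76 to -1.90), with a lower share in 14 of 16 plots. nrfA encodes the cytochrome c nitrite reductase that forms ammonium and differed by -4.53% (-7.77 to -1.17), lower in 11 of 16 plots. Adjusted over the list alone, both genes passed the threshold (adjusted p = 0.00987 each), while neither passed over all 526 families (adjusted p = 0.509 and 0.530). The adjustment over the list spans 2 genes and does not correct for the number of lists. For nitrogen 2 of 31 lists held a passing gene. The list as a whole differed by -5.02% (-7.95 to -2.01) and missed the threshold over the 31 lists (adjusted p = 0.0578). It passed with the deposited values unscaled (adjusted p = 0.0175) and with the number of detected probes as a covariate (adjusted p = 0.0346), but in none of the other 8 alternatives (adjusted p = 0.0670 to 0.8).

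The denitrification list took 4.12% ± 0.263 of the signal without and 4.04% ± 0.334 with nitrogen, a difference of -2.22% (-5.87 to 1.56), or -0.032 on the log2 scale. With unscaled values it was -0.065 (-0.119 to -0.011, adjusted p = 0.0839). Of its 6 measured families, 5 were lower in value and none passed adjusted over the list alone. The nitrite reductase genes nirK and nirS differed by -1.93% (-4.82 to 1.05) and -3.07% (-7.26 to 1.32), and the nitrous oxide reductase gene nosZ by -6.01% (-12.1 to 0.483). The ammonia monooxygenase family amoA, a marker of nitrifiers, was 1.2% of the signal both without and with nitrogen, a difference of 0.807% (-2.07 to 3.77). Its sign turned with unscaled values, with scaling by the median probe and with the detection covariate. It had the largest p of the nitrification list, and the values of the archaeal families AmoA_Arch_non_Cren and AmoA_Crenarchaeota are not given here. The hydroxylamine oxidoreductase gene hao differed by -7.67% (-16.9 to 2.60). nifH was 1.29% ± 0.165 without and 1.35% ± 0.101 with nitrogen, 5.45% higher (0.122 to 11.1) and higher in 13 of 16 plots. The nitrogen fixation list was 5.82% higher (0.271 to 11.7, adjusted p = 0.397), or 0.082 on the log2 scale. It was 0.049 (-0.041 to 0.139) with unscaled values and 0.038 (-0.034 to 0.110) without replicate 1. Of the assimilatory genes, nirA differed by -5.87% (-10.7 to -0.818) and nasA by -2.12% (-6.30 to 2.24), and of the ammonifying genes ureC differed by -2.17% (-5.93 to 1.74) and gdh by -7.01% (-16.7 to 3.83).

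All 3 measured families of the phosphorus use list had lower values with nitrogen, as had 54.4% of the 526 families, and the list differed by -6.12% (-12.3 to 0.497) without passing (adjusted p = 0.397). Phytase releases phosphate from phytate and differed by -9.25% (-16.8 to -0.990). ppk and ppx make and degrade polyphosphate, and they differed by -4.36% (-8.10 to -0.470) and -6.37% (-13.5 to 1.34). Phytase and ppk passed adjusted over the list alone (adjusted p = 0.0448 each), which again does not correct for the number of lists. All 6 families of the phosphate limitation list were lower in value, and the list differed by -3.25% (-6.51 to 0.126), but over probes detected in all 64 samples by -0.0025 on the log2 scale against -0.048. Its response regulator gene phoB differed by -5.12% (-9.71 to -0.290) and the phosphate transporter gene pstC by -4.53% (-8.68 to -0.187).

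Among carbon and other genes, 10 of the 14 families of the starch degradation list were higher in value with nitrogen, and the list was 8.45% higher (-1.50 to 19.4), while its member glucoamylase differed by -7.20% (-14.4 to 0.559). The cellulose gene cellobiase differed by -4.07% (-7.98 to 0.00614) and the limonene degradation gene limEH by 12.9% (-1.94 to 30.0). The methane monooxygenase gene pmoA was 4.70% higher (0.497 to 9.09), and the methanogen gene mcrA differed by -4.41% (-9.43 to 0.884). The cold shock list differed by -9.89% (-17.2 to -1.89, lower in 13 of 16 plots, adjusted p = 0.274), with cspB at -12.8% (-23.0 to -1.26). The terminal oxidase gene cydA differed by -11.2% (-18.9 to -2.72), the silver efflux gene SilA by -9.40% (-17.6 to -0.361) and the transporter family MFS_antibiotic by -3.39% (-6.06 to -0.651). The signs of pmoA and MFS_antibiotic turned when only probes detected in all 64 samples were summed, and that of mcrA turned with 2 principal components as covariates.

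In the test over all families, limma called 0 of 526 families for nitrogen, with 44 at an unadjusted p under 0.05 where 26.3 are expected by chance. The 5 families of smallest p had an adjusted p of 0.507 to 0.509 and were napA, nagK, mhpB, todC and nbzC. nagK was 0.0405% ± 0.00409 without and 0.0364% ± 0.00568 with nitrogen, -10.9% (-16.5 to -4.85), lower in 15 of 16 plots. mhpB differed by -17.9% (-28.1 to -6.39), the toluene dioxygenase gene todC by 17.2% (5.37 to 30.3) and nbzC by -23.2% (-35.9 to -8.08). These 4 are annotated as organic remediation genes, the largest category with 22.8% of the 526 families, and they differed in both directions. Of the 31 lists 0 passed (3 unadjusted), and of 38 taxa 0 passed (1 unadjusted), where Fusobacteria had the smallest p (8.85% higher, 0.734 to 17.6, in 14 of 16 plots, adjusted p = 0.868). Among 25908 probes limma called 0, with 1118 unadjusted against 1295.4 expected. Of the 234 families with at least 50 probes, 178 had a 95% interval for the nitrogen effect within about 10% of no difference.

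**Figure D2:**
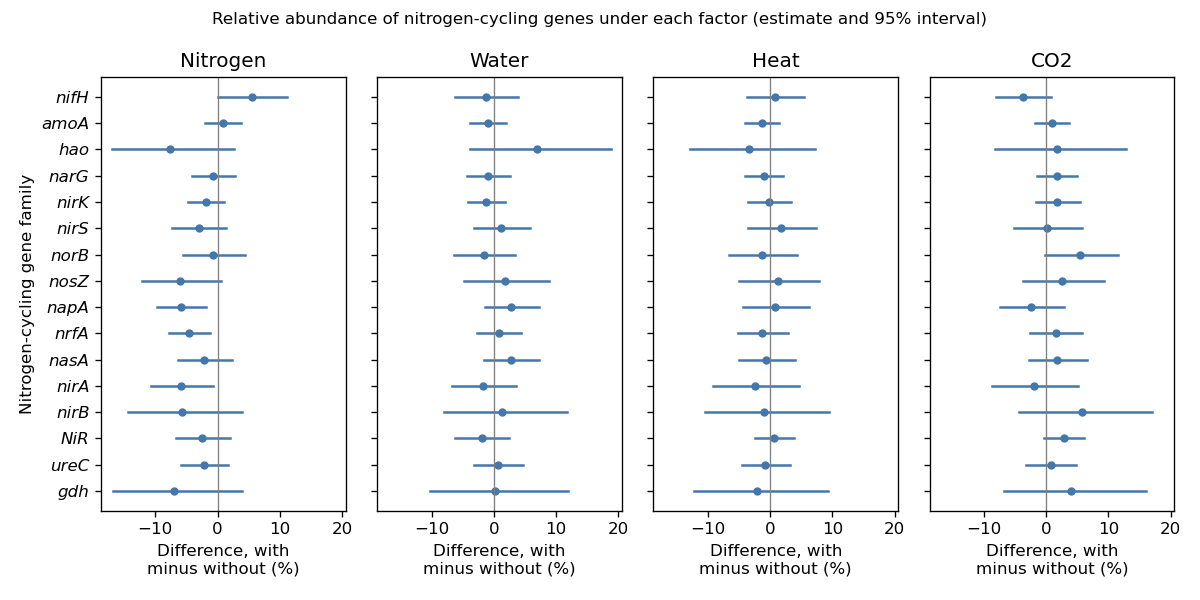
Difference in relative abundance (percent, with minus without the factor) of 16 nitrogen cycle gene families for nitrogen, water, heat and CO2; bars are 95% intervals. For nitrogen, napA (-5.91%), nirA (-5.87%) and nrfA (-4.53%) have intervals below 0 and nifH (5.45%) has its interval above 0.

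The water comparison asks the same of added precipitation. Of the 31 lists, 5 had an unadjusted p under 0.05 with water, each with a higher value, and none passed. Of all 526 families 61.2% had higher values with water (median 0.014 on the log2 scale), so counts of list members above 0 partly reflect this shift. The phosphate limitation list was 1.68% ± 0.132 (SD, n = 32 quadrants) without and 1.74% ± 0.114 with water, 3.93% higher (0.433 to 7.56), with 6 of 6 families higher in value, but over probes detected in all 64 samples the difference was 0.00088 on the log2 scale against 0.056. The alkaline phosphatase gene phoA was 8.30% higher (2.69 to 14.2) in 13 of 16 plots, the phosphate transporter genes pstA and pstC 6.52% (1.30 to 12) and 4.44% (-0.106 to 9.19). The cold shock list was 9.45% higher (0.526 to 19.2). Its gene cspA was 0.0101% ± 0.00200 without and 0.0119% ± 0.00250 with water, 17% higher (5.86 to 29.3) in 11 of 16 plots. cydA, the cytochrome bd oxidase used at low oxygen, was 15% higher (4.99 to 25.9) in 13 of 16 plots. Adjusted over the list alone, cspA (adjusted p = 0.00575), cydA (0.0244), phoA (0.0257) and pstA (0.0454) passed the threshold. They lie in 3 of the 31 lists, and this adjustment does not correct for the number of lists.

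The heat shock list was 3.11% higher with water (0.438 to 5.85, 5 of 6 families higher in value), with the chaperone genes grpE at 4.64% (0.279 to 9.19) and dnaK at 3.89% (-1.70 to 9.81). The nitrogen limitation list was 4.29% higher (0.0476 to 8.71, 3 of 3 families), with the glutamine synthetase gene glnA at 4.27% (-0.00929 to 8.73) and its repressor gene glnR at 7.02% (-1.23 to 16.0). The metal resistance list was 2.28% higher (0.218 to 4.38), with 16 of 18 families higher in value and SilA at 14.3% (3.92 to 25.7). The aluminium resistance family Al was 8.82% higher (2.66 to 15.4) and the drug efflux family SMR_antibiotics 4.65% (-0.100 to 9.63). The signs of grpE, dnaK, glnA, SMR_antibiotics, SilA and glnR, and of the heat shock, metal resistance and nitrogen limitation lists, turned when sums were limited to probes detected in at least 48 samples, in all 64, or in either set. In the nitrogen cycle, napA differed by 2.81% (-1.39 to 7.19), and the nitrogen fixation list by -1.81% (-6.96 to 3.63), a sign that turned with scaling by the median probe. Phytase differed by 3.07% (-5.53 to 12.4).

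For water limma called 0 of 31 lists, and each of these 5 had an adjusted p of 0.277. The oxygen limitation list alone passed without replicate 2 (adjusted p = 0.0146). Of 526 families 0 passed for water (30 unadjusted). The 5 of smallest p were cspA, cydA, helicase_family_4, phoA and Al (adjusted p = 0.494 each), of which the phage gene family helicase_family_4 was 23.3% higher (7.37 to 41.6). Of 38 taxa 0 passed (3 unadjusted, adjusted p = 0.442). Fibrobacteres were 6.82% higher (1.09 to 12.9), viruses 4.59% higher (0.609 to 8.73, with the opposite sign over probes detected in all 64 samples), and Actinobacteria differed by -2.13% (-4.06 to -0.160), a sign that turned with scaling by the median probe. Among 25908 probes 0 passed (759 unadjusted).

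**Figure D3:**
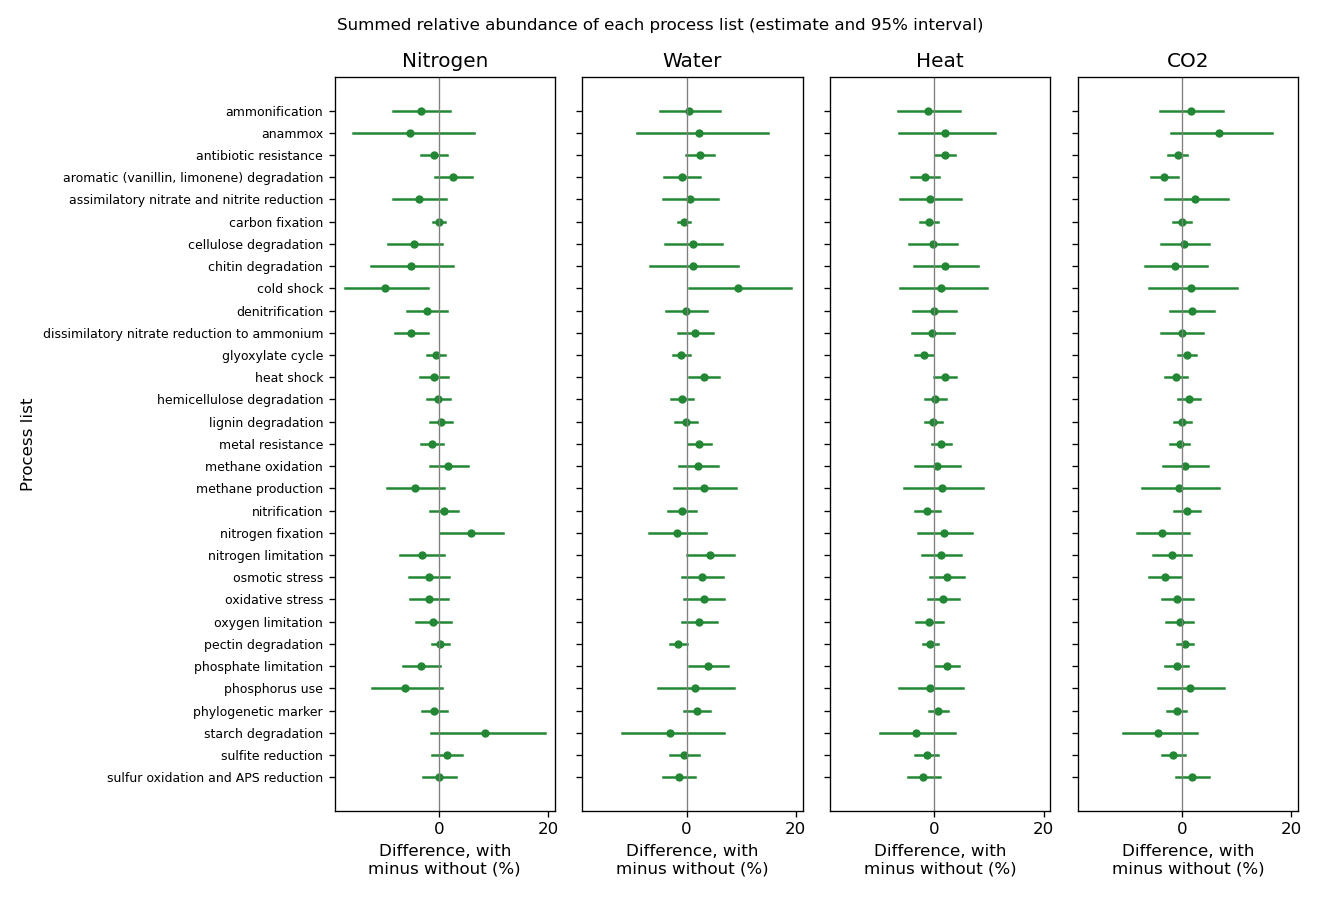
Difference in relative abundance (percent, with minus without the factor) of the 31 lists of gene families for nitrogen, water, heat and CO2; bars are 95% intervals. The list for dissimilatory nitrate reduction to ammonium lies at -5.02% for nitrogen, and no list passed the threshold for any factor.

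The heat comparison sets 8 warmed against 8 unwarmed plots. Heat shock genes were higher in value with heat in 6 of 6 measured families, but so were 321 of all 526 families (median 0.013 on the log2 scale, against 0.028 for the list). The list was 0.893% ± 0.0309 (SD, n = 8 plots) without and 0.910% ± 0.0226 with heat, 1.97% higher (-0.0194 to 4.0), and it was higher in all 4 replicate numbers. The chaperone genes dnaK and grpE were 5.55% (0.0835 to 11.3) and 2.79% (-0.808 to 6.52) higher, and their repressor gene hrcA 2.11% (-0.368 to 4.66). The cold shock gene cspA differed by -6.37% (-13.9 to 1.85). The glyoxylate cycle list differed by -1.87% (-3.46 to -0.253), lower in value in 4 of 4 families, among them the malate synthase gene AceB at -1.98% (-4.11 to 0.193) and the isocitrate lyase gene AceA at -1.52% (-4.57 to 1.6), whose sign turned without replicate 2.

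The antibiotic resistance list was 1.90% higher with heat (0.102 to 3.72, 8 of 9 families), with SMR_antibiotics 4.19% higher (0.992 to 7.48). The phosphate limitation list was 2.27% higher (0.0773 to 4.51, 6 of 6 families), with pstA at 3.57% (-0.410 to 7.71) and phoB at 2.85% (-0.527 to 6.35). The osmoprotectant transporter gene proV differed by 3.30% (-0.174 to 6.89). In the nitrogen cycle, amoA differed by -1.36% (-4.01 to 1.37) and the nitrogen fixation list by 1.79% (-3.08 to 6.91). With sums over probes detected in all 64 samples, the signs of grpE, SMR_antibiotics, the antibiotic resistance list and the nitrogen fixation list turned, and with their mean log2 signal that of dnaK did.

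For heat, limma called 0 of 526 families (28 unadjusted) and 0 of 31 lists (3 unadjusted, smallest adjusted p = 0.403). The 5 families of smallest p had an adjusted p of 0.747 each. The fungal families hmgB_fungi and alpha_galactosidase_fungi were 12.6% (4.13 to 21.8) and 8.75% (2.23 to 15.7) higher, the aromatic degradation families nicdehydr and catechol_B 13.4% (3.42 to 24.4) and 4.78% (1.27 to 8.41) higher, and HcaB differed by -6.28% (-10.3 to -2.02). Of 38 taxa 0 passed (4 unadjusted). Actinobacteria were 19.2% ± 0.758 without and 18.9% ± 0.563 with heat, -1.51% (-2.49 to -0.520) and lower in all 4 replicate numbers (adjusted p = 0.166), and they passed without replicate 1 (adjusted p = 0.00571). Firmicutes were 1.43% higher (0.162 to 2.71, adjusted p = 0.352), with the opposite sign over probes detected in all 64 samples. Among 25908 probes 0 passed (663 unadjusted).

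The CO2 comparison sets 8 plots at 680 ppm against 8 at 380 ppm. The potassium uptake genes kup and ktrBD, among the 5 families of smallest p, did not pass over all families (adjusted p = 0.920 each). kup was 0.409% ± 0.0297 (SD, n = 8 plots) at ambient and 0.443% ± 0.0213 at elevated CO2, 9.05% higher (3.33 to 15.1), and ktrBD was 9.97% higher (3.34 to 17). The 7 potassium transport families of the array, summed after these values were seen, differed by 4.43% (-3.18 to 12.6), and trkA among them by -0.162% (-8.60 to 9.05). Of the starch degradation list, 10 of 14 families were lower in value and the list differed by -4.38% (-10.9 to 2.64). The alpha-amylase genes of Proteobacteria (amyA_Proteobacteria) were 1.39% ± 0.119 at ambient and 1.17% ± 0.207 at elevated CO2, -16.3% (-27.4 to -3.51), and amyA_other differed by -10.4% (-19.7 to -0.0316). limEH, for limonene breakdown, differed by -13.9% (-22.7 to -4.10) in 3 of 4 replicate numbers and passed adjusted over the list alone (adjusted p = 0.0406). That adjustment does not correct for the number of lists, and for CO2 1 of 31 lists held a passing gene.

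In the nitrogen cycle, 6 of 6 denitrification families were higher in value at elevated CO2 and the list was 1.78% higher (-2.14 to 5.86), with its sign turned without replicate 4. The nitric oxide reductase gene norB was 5.46% higher (-0.260 to 11.5), the assimilatory gene NiR 2.81% (-0.340 to 6.07), and nifH differed by -3.77% (-8.05 to 0.720). The nitrogen fixation list differed by -3.61% (-8.22 to 1.24). The osmotic stress list differed by -3.15% (-6.09 to -0.129), with proV at -3.44% (-6.69 to -0.0850), and the chaperonin gene groEL by -5.71% (-10.3 to -0.871). The aromatic degradation list differed by -3.28% (-5.79 to -0.698), with 2 of 4 families lower in value. The signs of proV and of the osmotic stress and aromatic lists turned over probes detected in all 64 samples.

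For CO2, limma called 0 of 526 families (21 unadjusted), 0 of 31 lists (2 unadjusted, smallest adjusted p = 0.539) and 0 of 25908 probes (1109 unadjusted). The 5 families of smallest p (adjusted p = 0.920 each) were kup, ktrBD, limEH, the phthalate degradation gene ophC (10.4% higher, 3.82 to 17.4) and the oomycete virulence family necrosis_Oomycetes (11.2% higher, 3.38 to 19.7). Of 38 taxa 0 passed (2 unadjusted). Bacteroidetes were 2.81% ± 0.118 at ambient and 2.72% ± 0.0454 at elevated CO2, -2.93% (-4.82 to -0.999) in 3 of 4 replicate numbers (adjusted p = 0.177). They passed without replicate 2 (adjusted p = 0.00422) and without the 3 arrays of fewest detected probes (adjusted p = 0.0111). Actinobacteria were 1.27% higher (0.265 to 2.28, adjusted p = 0.291), with the opposite sign under scaling by the median probe.

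The factorial design also asks whether the effect of 1 factor depends on another. The effect of water on the share of Proteobacteria differed between the CO2 levels. The share was 44.8% ± 0.691 (SD, n = 16 quadrants) without and 44.4% ± 0.638 with water at ambient CO2, and 44.3% ± 0.559 without and 45.1% ± 0.812 with water at elevated CO2. The share was higher with water in 3 of 8 ambient plots and in 6 of 8 elevated plots. The difference of the water effects was 0.040 on the log2 scale (SE 0.010, adjusted p = 0.00789 over the 38 taxa and 0.0473 over all 6 interactions). This test and those of the other taxa below take their spread from quadrants within plots, while CO2 was applied to plots. Among plots the water effect on Proteobacteria was -0.015 ± 0.030 (SD, n = 8) at ambient and 0.026 ± 0.033 at elevated CO2. The adjusted p does not rest on this spread among plots. Verrucomicrobia went the other way, from 0.998% to 1.03% with water at ambient CO2 (higher in 6 of 8 plots) and from 1.03% to 0.991% at elevated CO2 (higher in 0 of 8 plots), a difference of -0.094 (SE 0.029, adjusted p = 0.0396) whose sign turned both with unscaled values and with scaling by the median probe. Microsporidia, read from 4 probes with 0.00522% of the signal, differed by -0.80 (SE 0.25, adjusted p = 0.0396). Over all 6 interactions the values of Verrucomicrobia and Microsporidia had an adjusted p of 0.238. Under other settings Proteobacteria passed in 5 of 10, Verrucomicrobia in 1 of 10 and Microsporidia in 1 of 9.

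**Figure D4:**
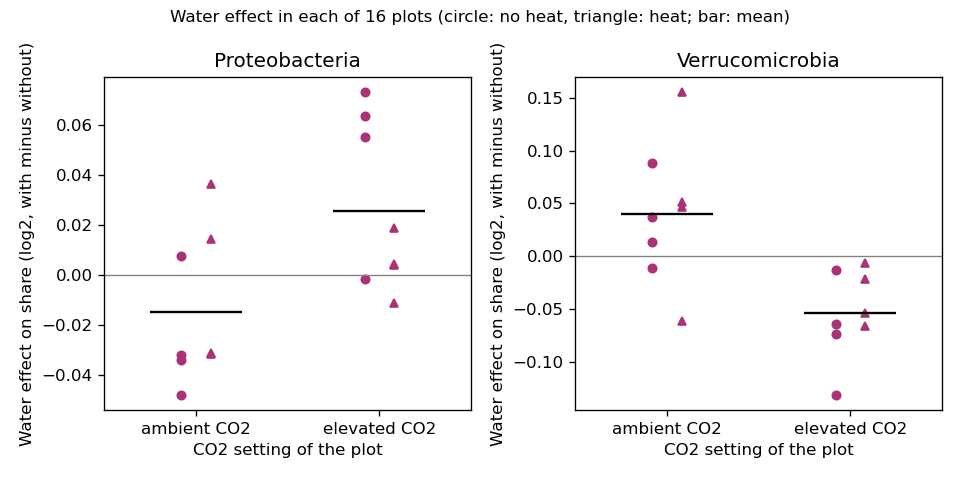
Effect of water on the relative abundance of Proteobacteria and Verrucomicrobia (log2, with minus without water) in each of the 16 plots, by CO2 level; circles are unwarmed and triangles warmed plots, and the bar is the mean. For Proteobacteria 3 of 8 ambient and 6 of 8 elevated plots lie above 0, for Verrucomicrobia 6 of 8 and 0 of 8.

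These taxon tests were added after the data were seen, and the sign for Proteobacteria turned when only probes detected in all 64 samples were summed as a share of the whole array (-0.092). With either scaling alternative, or with the number of detected probes as a covariate, none of the 38 taxa passed for water and CO2, and without replicate 3 none did. The value for Proteobacteria was then 0.14 (SE 0.051, adjusted p = 0.172) unscaled, 0.16 (SE 0.064, 0.283) with the median probe, 0.031 (0.0832) with the covariate and 0.028 (0.237) without replicate 3. Of 330 gene families summed over proteobacterial probes, 62.4% had positive values for this interaction, against 50.5% of 430 families summed over probes of other taxa. The 330 families are built from the same probes as the Proteobacteria total, and both sets are shares of the same array signal. These counts therefore describe that result and are not separate support for it. An unadjusted p under 0.05 was reached by 63 of the 330 (48 positive) and 42 of the 430 (23 positive), and none passed in either set. Over all 526 families limma called 0 for water and CO2, with 61 unadjusted and a smallest adjusted p of 0.214. It also called 0 for nitrogen and water (17 unadjusted), nitrogen and CO2 (13), nitrogen and heat (8), water and heat (6), and CO2 and heat (29). Without replicate 4, 4 families passed for water and CO2, which were kdpA, trkGH and pcpE with positive and per_fun with negative values.

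Each treated group was also set against the untreated control (4 quadrants each). limma called 0 families for each of the 15 treatments. The count at an unadjusted p under 0.05 was 56 for nitrogen with water, 52 for nitrogen alone, 41 for nitrogen with CO2, 39 for nitrogen with heat and CO2, 31 for water, 21 for CO2, 15 for heat, 12 for all 4 factors, 10 for heat with water, 8 for each of nitrogen with CO2 and water, nitrogen with heat, and nitrogen with heat and water, 3 for water with heat and CO2, 1 for CO2 with water and 0 for heat with CO2. The family of smallest p was phoB for nitrogen alone (log2 difference -0.34, SE 0.10, adjusted p = 0.443) and for nitrogen with CO2 (-0.35, SE 0.11, adjusted p = 0.492). It was the fungal drug resistance family MFS_fungi for nitrogen with water (0.71, SE 0.18, adjusted p = 0.147). These families were chosen after their values were seen. Without control replicate 1 the counts were 21 for nitrogen with water, 22 for nitrogen, 30 for nitrogen with CO2, 26 for nitrogen with heat and CO2, 12 for water, 6 for CO2, 5 for heat, 5 for all 4 factors, 3 for nitrogen with heat, 5 for nitrogen with heat and water, 13 for nitrogen with CO2 and water, 12 for heat with water, and 5 or fewer for the rest. Without replicate 4 nitrogen alone gave 10.

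Relative to the control, nirK, nirS, nosZ, nrfA and ureC had lower values in 15 of 15 treatments each, while the other 4 nitrogen genes examined (narG, amoA, nifH and napA) went both ways. The log2 differences were -0.14 to -0.014 for nirK, -0.20 to -0.030 for nirS, -0.30 to -0.024 for nosZ, -0.18 to -0.0064 for nrfA and -0.15 to -0.0091 for ureC. All 15 comparisons use the same 4 control arrays, so a family that is high in these arrays by chance is lower in every treatment. Of the 526 families, 10.1% had all 15 treatments on one side of the control, and 6.27% had all 15 below it. In simulated data with no treatment effect 12.2% had all 15 on one side (lowest 9.13% and highest 16.3% of 100 simulations). The simulation drew families independently, so it cannot say how often related genes lie below the control together. Without control replicate 1 the counts were 14 for nirK, 13 for nirS, 12 for nosZ, 15 for nrfA and 12 for ureC, and with unscaled values nrfA was lower in 14.

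Composition of the whole array was compared on Bray-Curtis distances. Nitrogen accounted for 1.82% of the variation (permutation p = 0.203), water for 1.28% (0.541), CO2 for 4.14% of that among plots (0.556) and heat for 3.96% (0.609). With each replicate number left out in turn, the shares were 1.51% to 2.94% for nitrogen and 1.23% to 2.33% for water. They were 3.99% to 8.05% for CO2 and 4.97% to 6.80% for heat, and the lowest permutation p was 0.124. The Shannon index was 10.2 without and with each factor (differences -0.0428 for nitrogen, 0.0331 for water, 0.0305 for heat and -0.00869 for CO2), and no difference passed the permutation test. Total signal, in units of 1000000, was 790.0 ± 43.8 without and 773 ± 53.2 with nitrogen, a difference of -17.1 (permutation p = 0.163).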

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

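Tests chosen only after a result was seen were the counts over redrawn labels, the taxon test of water and CO2, both shares of the probes detected in all 64 samples, the comparison of arrays within a plot, the detection covariate and the test without the families of highest signal, while the values as a share of the whole array used a filter fixed beforehand. What the covariate and the families of highest signal would show was written down before their own values were seen.

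Arrays with the same replicate number resembled each other across treatments. Their mean correlation exceeded that of arrays with other numbers by 0.0388 (permutation p = 0.0001, the smallest these permutations can give). Replicate number accounted for 15.6% of the variation in composition, plot for 30.7% and the number of detected probes for 14.3% (permutation p = 0.001 each, the smallest possible here). A term with more levels takes more by chance, and the share of plot includes that of replicate number, within which the plots lie. A difference in the number of detected probes is argued against as the whole cause, because the excess was 0.0389 after the trend on detected probes was removed. Shared soil of a plot is argued against too, because the correlation within a plot minus that between plots of the same number was -0.0060 (upper 95% limit 0.012, below the 0.019 asked of this explanation). The location of the replicate blocks on the site and a laboratory batch that follows the replicate number stay open, since the labels give no batch, and no biological explanation was tested.

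The effect of water on the share of Proteobacteria differed with CO2 by 0.040 on the log2 scale (95% interval 0.020 to 0.061), and this pattern stood out as a difference between groups, as did Verrucomicrobia (-0.094) and Microsporidia (-0.80). The intervals given here take their spread from quadrants within plots, not from the plots that received CO2. A few dominant gene families are argued against as the whole cause, because without the 10 proteobacterial families of highest signal, which hold 21.1% of the proteobacterial signal, the value was 0.037 (0.012 to 0.062). The lower limit of this interval leaves room for them as a large part of the cause. The number of detected probes stays open, because with it as a covariate the value was 0.031 (0.010 to 0.051), an interval that reaches from a small part of the effect to all of it, and no taxon passed the threshold. Probes near the detection limit stay open as well: over probes detected in all 64 samples the value was 0.026 (0.011 to 0.040) as a share of those probes, but -0.092 (-0.214 to 0.031) as a share of the whole array, and the first denominator was chosen after the second had been seen, because the median of all families in that setting was -0.13, against 0.026 over all probes. A biological dependence of the water effect on CO2 therefore cannot be told apart from these causes.

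The share of napA and nrfA was lower with nitrogen (-0.074 on the log2 scale, 95% interval -0.119 to -0.029). The number of detected probes is argued against as the cause, because the value was -0.079 (-0.124 to -0.034) with it as a covariate. Probes that drop in and out at the detection limit are argued against by the value over probes detected in all 64 samples, -0.099 (-0.167 to -0.031) as a share of those probes. The same caveat on the denominator holds. As a share of the whole array the value was -0.080 (-0.178 to 0.018), an interval that holds 0, so on that share the explanation stays open. A lower abundance of these genes with added nitrate is one hypothesis left, found and tested on the same data, and the value missed the threshold over 31 lists.

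Labels were redrawn 100 times, the real labels included, within plots for nitrogen and water and among plots of a replicate number for CO2 and heat, and families at an unadjusted p under 0.05 were counted because the adjusted counts were 0. For nitrogen 17 of 100 gave at least the real 44 families (highest other 94), for water 33 gave 30 (132), for heat 35 gave 28 (79) and for CO2 43 gave 21 (67). Among interactions, 67 reached 17 for nitrogen and water (86), 70 reached 13 for nitrogen and CO2 (82), 94 reached 8 for nitrogen and heat (98), 6 reached 61 for water and CO2 (136), 88 reached 6 for water and heat (80) and 35 reached 29 for CO2 and heat (75). Of process lists, 24 redrawn sets gave at least 3 for nitrogen (13), 12 gave 5 for water (12), 35 gave 3 for heat (13) and 30 gave 2 for CO2 (11). Of taxa, 62 gave at least 1 for nitrogen (12), 31 gave 3 for water (13), 27 gave 4 for heat (10) and 56 gave 2 for CO2 (11). With 50 redrawn sets of probes, 22 reached 1118 for nitrogen (5670), 34 reached 759 for water (5677), 35 reached 663 for heat (3516) and 26 reached 1109 for CO2 (3943). Chance could not be excluded for any of these counts. Some redrawn labels gave several times the real count, and whether a structure of the samples other than the treatments causes this was not tested. For taxa past the adjusted threshold under water and CO2, 4 of 100 gave at least the real 3 (highest other 7), but this count was tested because taxa had passed there, and it is the only share under 0.05 among the many given here, so chance stays open for it as well.

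For single treatments against the control all 35 splits of the 8 arrays were counted, with the plot correlation held fixed. As many families as the real number were reached by 3 splits for nitrogen with water (56, highest other 57), 4 for nitrogen (52, 69), 7 for nitrogen with heat and CO2 (39, 61), 10 for nitrogen with CO2 (41, 88), 11 for heat (15, 59), 15 for water (31, 71) and 17 for CO2 (21, 68). The number was 27 for all 4 factors (12, 61), 28 for nitrogen with CO2 and water (8, 89), 29 for heat with water (10, 64), 29 for nitrogen with heat (8, 50), 34 for water with heat and CO2 (3, 54), and 35 each for CO2 with water (1, 90), heat with CO2 (0, 52) and nitrogen with heat and water (8, 77). No treatment had a share of splits under 0.05. These splits keep neither the arrays of a plot nor those of a replicate number together, and swaps within replicate numbers give 8 splits, too few for a share under 0.05.

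On 4 measures, 4 arrays stood far from the others of their group of 4, in 8 of 64 tests. The measures share the same arrays, so these 8 are not independent and cannot be set against the 1 in 20 groups that chance gives for 1 measure. Replicate 3 of CO2 with water had 40936 detected probes against 38745 to 39048 in the others, and a total signal of 851 units of 1000000 against 805 to 809.5. Replicate 2 of nitrogen with heat and CO2 had 18760 detected probes against 32275 to 34896, and its mean correlation with the other arrays was 0.584 against 0.727 to 0.755. Replicate 2 of nitrogen with heat and water had 21535 detected probes against 38608 to 41606, a total signal of 664 units against 799 to 823 and a Shannon index of 9.79 against 10.3 to 10.4. Replicate 1 of the control had a mean correlation with the other arrays of 0.539 against 0.744 to 0.769.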

How the results depend on the processing

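The settings with the number of detected probes or 2 principal components as covariates, without the 3 arrays of fewest detected probes and without control replicate 1 were chosen after seeing the data, as were the interaction tests on taxa. limma called 0 gene families in each of 17 alternatives for every main effect and interaction except water and CO2, where 15 of 17 gave 0, and in each of 240 alternatives for the single treatments. Unadjusted counts ranged from 9 to 65 for nitrogen, 7 to 64 for water, 2 to 48 for heat, 1 to 40 for CO2 and 30 to 111 for water and CO2. For probes 0 passed in each of 11 alternatives per main effect. Of 1662 values of the 115 named genes, lists and taxa under other settings, 1611 kept their sign and 51 turned. None of those that turned had a p under 0.05, taken unadjusted for genes and adjusted for lists and taxa. The unadjusted p of lists and taxa that turned was not counted. Of the values that kept their sign, 199 were over 1.5 times smaller, among them 25 of 89 over probes detected in all 64 samples, 34 of 79 over probes detected in at least 48 and 36 of 78 with 2 principal components. The threshold was passed only there by 5 values and lost by 22, of which 3 had also turned (Verrucomicrobia under both scalings, Proteobacteria over probes detected in all 64 samples). For lists and taxa whose 95% interval was clear of 0 as reported, it held 0 in 114 of 235 other values, and where it held 0 as reported it was clear of 0 in 7 of 100. The treatments below the control numbered at least 11 of 15 for nirK, 10 for nirS, 11 for nosZ, 10 for nrfA and 10 for ureC. The lowest signal on an array was 2998 to 9915, and whether scaling or the visibility of weak probes set it was not tested. Where a cause is not given, the cause was not tested.

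Arrays of a plot did not resemble each other more than arrays of other plots with the same replicate number. Deviations from the group means correlated at 0.082 on average within a plot, at 0.116 between plots of the same number and at -0.054 between numbers, and 8 of 16 plots lay above 0.1 (range -0.044 to 0.215). A model without block drops plot for nitrogen, water and their interactions, and the replicate number for CO2, heat and their interaction. Without the plot block the taxa called for water and CO2 numbered 1 (Proteobacteria) in place of 3. Without either block no other count of calls moved. Not every array correlated best with an array of its own number. With the replicate block added to plot as a random block, the 15 treatments gave 0 families each.

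The deposited values without further scaling gave 1 list for nitrogen (dissimilatory nitrate reduction to ammonium, -0.107) and 0 taxa for water and CO2, with Verrucomicrobia at 0.0051, amoA under nitrogen at -0.021 and trkA under CO2 at 0.00011. Division by the median probe gave 0 taxa for water and CO2, with Verrucomicrobia at 0.028, amoA under nitrogen at -0.0019, the nitrogen fixation list under water at 0.014, and Actinobacteria at 0.0096 under water and -0.0054 under CO2. The median of all families for water and CO2 was 0.125 unscaled and 0.148 with the median probe, against 0.026 with array totals, and that for nitrogen and water 0.116 with the median probe against 0.031. With the number of detected probes as a covariate, lists for nitrogen numbered 1 (the same list, -0.079), taxa for water and CO2 numbered 0, amoA under nitrogen was -0.0040 and trkA under CO2 0.0076. With 2 principal components, 1 family (mauAB) passed for water and CO2, mcrA under nitrogen was 0.00075 and trkA under CO2 0.013. Without the 3 arrays of fewest probes, 1 taxon passed for CO2 (Bacteroidetes) and 1 for water and CO2 (Proteobacteria), and trkA under CO2 was 0.0085.

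Sums over probes detected in all 64 samples, as a share of the whole array, gave pmoA -0.034 and MFS_antibiotic 0.0089 under nitrogen. Under water they gave grpE -0.045, dnaK -0.013, glnA -0.019, SMR_antibiotics -0.073, viruses -0.059, and the lists for heat shock -0.065, metal resistance -0.044 and nitrogen limitation -0.022. Under heat they gave SMR_antibiotics -0.031, grpE -0.011, Firmicutes -0.017, and the lists for antibiotic resistance -0.042 and nitrogen fixation -0.031. Under CO2 proV and the osmotic stress list were 0.014 each, trkA 0.011 and the aromatic degradation list 0.0059, and for water and CO2 Proteobacteria were -0.092 while 2 taxa passed (Nitrospirae and Verrucomicrobia). The mean log2 signal of the same probes gave pmoA -0.033 under nitrogen, grpE -0.041, dnaK -0.0062, glnA -0.029 and SMR_antibiotics -0.091 under water, SMR_antibiotics -0.018, dnaK -0.0090 and grpE -0.0100 under heat, and proV 0.017 and trkA 0.0084 under CO2. Probes detected in at least 48 samples gave SilA -0.0088, grpE -0.014, glnR -0.033 and SMR_antibiotics -0.00083 under water, and trkA 0.0049 under CO2.

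With each replicate number left out in turn, families for water and CO2 numbered 0 to 4 (4 without replicate 4), lists for water 0 to 1 (oxygen limitation, without replicate 2), taxa for heat 0 to 1 (Actinobacteria, without replicate 1), taxa for CO2 0 to 1 (Bacteroidetes, without replicate 2) and taxa for water and CO2 0 to 2. AceA under heat ranged from -0.034 to 0.0039 the denitrification list under CO2 from -0.00042 to 0.044 and trkA under CO2 from -0.018 to 0.035. The CO2 difference ranged from -1088 to 88.7 detected probes, from -0.0249 to 0.00205 in the Shannon index and from -3.74 to 4.97 units of 1000000 in total signal. The difference in detected probes ranged from 625 to 2183 for water, 350 to 1194 for heat and -2140 to -1026 for nitrogen. In the Shannon index it ranged from 0.00873 to 0.0499 for water, 0.0151 to 0.0456 for heat and -0.0657 to -0.0306 for nitrogen. The nitrogen difference in total signal ranged from -19.9 to -15.6 such units, with a permutation p of 0.0374 without replicate 2 and 0.163 with all arrays.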

Other observations

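At elevated CO2 some further potassium transport families had higher values. These families, and the tests of their sum, of subcategories and of array correlations, were chosen after values were seen. The potassium efflux family kefBC was 0.749% ± 0.0423 (SD, n = 8 plots) at ambient and 0.809% ± 0.0519 at elevated CO2, 8.47% higher (95% interval 2.23 to 15.1). The fungal transporter family trk_fungi was 11.5% higher (2.46 to 21.4) and the potassium ATPase gene kdpA 8.63% (-1.09 to 19.3). Each of these 3 had an adjusted p of 0.920 in limma. Of the remaining families, trkGH was 1.74% at ambient and 1.83% at elevated CO2, a difference of 4.43% (-4.03 to 13.6, 1183 probes), and trkA (1065 probes) was 1.79% at both, a difference of -0.162% (-8.60 to 9.05) whose sign turned under 8 other settings. The 7 potassium transport families on the array, summed, took 5.62% of the signal and were 4.43% higher at elevated CO2 (-3.18 to 12.6) in 3 of 4 replicate numbers. Their summed share differed by -0.107% (-9.22 to 9.93) with nitrogen, by -1.05% (-10.1 to 8.89) with water and by 2.25% (-5.20 to 10.3) with heat.

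Grouped by the 102 gene subcategories of the array's annotation, limma called 0 for every main effect, with 6 at an unadjusted p under 0.05 for nitrogen, 12 for water, 8 for heat and 4 for CO2. The smallest adjusted p was 0.177, 0.375, 0.439 and 0.817 in that order.

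By replicate number the mean number of detected probes was 34163 (number 1), 32588 (number 2), 39367 (number 3) and 35903 (number 4), with 16 arrays each. The mean correlation of arrays of the same treatment minus that of arrays of other treatments was -0.0057 (permutation p = 0.778). Of the 68694 probes, 374 had no lineage and 788 no organism in the annotation.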
